A study of Homo sapiens with 26 samples.

How the data were processed

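RNA was measured by sequencing of polyA-selected libraries from human small cell lung cancer cell lines. Per the labels, 12 of the 26 libraries came from a knockout experiment in COR-L311, NCI-H1048, NCI-H211 and NCI-H526, each infected by lentivirus with 1 control guide RNA (sgNeg) or either of 2 guides against POU2F3 (sgPOU2F3). NCI-H211 and NCI-H1048 were harvested 4 days after infection, and NCI-H526 and COR-L311 after 5 days. The other 14 libraries came from exponentially growing parental lines, 1 library per line: those 4 lines and 10 others. The harvest day and the line differ together, so the effect of the day cannot be separated from the line.

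The authors deposited 5 tables of FPKM (fragments per kilobase of transcript per M mapped fragments), 1 for each knockout line and 1 for the 14 parental lines. The labels call the parental table RPKM, while its own name says FPKM. The submitters' notes name TopHat2, Cufflinks and Cuffdiff and the build hg19, without versions, the role of each, the annotation, or how libraries were scaled across columns. Each knockout table holds 1 sgNeg column and 1 sgPOU2F3 column for the 2 guides, so the deposited value combines the guides, in a way the files do not state. It is used here as the authors' value, without a spread between guides. Tests within a line, the agreement of the 2 guides, the test of a difference between lines, fits on single guides and the fit with guides as replicates were planned, and could not be run on combined columns.

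Values were taken as log2(FPKM + 1). In the knockout comparison, genes needed an FPKM of at least 1 in at least 4 of the 8 columns, where the plan had counted the 12 libraries. The fit used limma 3.58.1 in R 4.3.3 with a trend in the variance, with line and arm as terms and 3 residual degrees of freedom, so that each ratio was formed within 1 line and 1 table. The line is the unit of replication, n = 4 lines. The parental comparison used the same limma test on 4 lines against 10, for genes with an FPKM of at least 1 in at least 4 of 14 libraries. The threshold was a Benjamini-Hochberg adjusted p of 0.05. Within a line, genes were counted by size alone, a log2 ratio of at least 1 in either direction, with no test.

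The 28 gene lists, with 546 memberships, were fixed before the data were examined, as were the comparisons, the rule for named genes and the other settings tried. Lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Within a line, the median ratio of a list was set against 10000 random lists of genes matched on expression and given as a percentile, not a p. Counts "adjusted over the list alone" use the same p-values, adjusted within the list. Several lists share members, such as POU2F3, ALOX5 and TRPM5. A set of up to 100 genes in each direction was to be taken from the parental test into the knockout data. Only 28 higher and 5 lower genes passed, so larger and smaller set sizes give the same sets.

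The named genes are POU2F3, NEUROD1 and YAP1, and, across lines, genes past the threshold with the same sign in all 4 lines. In a direction with fewer than 10 such genes, the next by p with a mean log2 ratio of at least 1 were added, up to 10, and are named as not passing. In each line they are the 5 largest falls and 5 largest rises, in the parental comparison the 15 largest differences in each direction past the threshold, and in each list up to 4 members with the smallest p, and those past the threshold where there are 5 or fewer. Short non-coding, unnamed and sex-linked marker transcripts were passed over. Some genes that the rule takes are not reported here. The rule had asked for the same sign with both guides, which was read here as the same sign in the combined columns.

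The tables give no counts. Depth was estimated from the smallest steps between FPKM values of genes with 1 annotated transcript, with transcript lengths from GENCODE on GRCh38, a different build from that of the tables. This gave 9.68 to 15.7 M fragments (M, mega) for the sgNeg columns and 10.0 to 31.5 M for the parental columns. Steps in the combined columns give 15.7 to 24.7 M. These are estimates, and the precision of a low value depends on them. The genes at 0 were 18.3% to 21.5% in the sgNeg columns and 13.8% to 15.9% in the combined columns, so a gene near 0 is more often listed above 0 in sgPOU2F3.

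Each of the 8 columns of the knockout tables was checked against the 14 parental libraries by rank correlation over genes, and 8 of 8 were closest to their own line. The methods were tested on simulated data with known changes. The knockout fit recovered 67.2% of genes changed by 1 on the log2 scale and 92.5% of those changed by 2, with 8 false calls among 12542 genes. The parental fit recovered 19.4%, 61.2% and 98.5% of genes changed by 1, 2 and 3, with 7 false calls among 13827 genes. In both simulations only genes with a mean log2(FPKM + 1) above 3 were changed, by the same amount in each changed line. Noise was drawn independently for each gene. The recovered shares therefore do not hold for low genes or for changes that differ in size between lines.

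The other settings were a pseudocount of 0.1, no filter, a filter at an FPKM of 5, quantile normalization within each table, limma without trend, ratios centred on their median, no term for the line, Spearman in place of Pearson correlation, other list tests and leaving out each line in turn. Figures were drawn with matplotlib 3.10.9.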

Results

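The series measured gene expression in small cell lung cancer lines, with the question of what the transcription factor POU2F3, known from tuft cells (chemosensory epithelial cells), controls in the lines that express it. The knockout experiment compared 2 POU2F3 guides, combined by the authors into 1 value per line, with 1 control guide (sgNeg) in 4 lines. A separate set of 14 parental lines, 1 library each, held the same 4 lines and 10 others. Estimated depth was 11.5 M fragments (M, mega) for COR-L311 sgNeg, 11.1 M for NCI-H1048, 9.68 M for NCI-H211 and 15.7 M for NCI-H526. Parental libraries ranged from 10.0 M in COR-L311 to 31.5 M in NCI-H146 and NCI-H69. In NCI-H889, 1 gene, NDUFS5, was listed at 12983.8 FPKM, the highest value in any library. The tables hold 1 value per line and arm, so values for a single line carry no error.

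The first comparison asked what changed after POU2F3 knockout across the 4 lines. KRT19, a keratin of simple epithelia, rose by 2.02 ± 0.27 on the log2 scale (SD, n = 4 lines, adjusted p = 0.032), from 15.5 to 74.6 FPKM in NCI-H1048 and from 38.2 to 129 FPKM in NCI-H211. BMF, a BH3-only protein that promotes apoptosis, rose by 1.31 ± 0.15 (SD, n = 4 lines, adjusted p = 0.044), from 62.1 to 174 FPKM in COR-L311. Both were higher in 4 of 4 lines. Falls were ranked by p among genes lower in 4 of 4 lines with a mean log2 ratio of at least 1 in size. The first of these included genes of the tuft cell programme and of eicosanoid synthesis, none of them past the threshold. RGS13, a regulator of G protein signaling, had a mean log2 ratio of -2.77 ± 1.20. ALOX5, the enzyme that starts leukotriene synthesis, stood at -1.83 ± 0.62, and PLA2G4A, a phospholipase that releases arachidonic acid, at -1.77 ± 0.81. The kinase gene BMX stood at -1.64 ± 0.83, and PSD2 at -2.08 ± 1.09.

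POU2F3 itself (GRCh38 chromosome 11, 120236640 to 120319944) had a mean log2 ratio of -1.77 ± 1.46 (SD, n = 4 lines, adjusted p = 0.40, lower in 4 of 4 lines). Its FPKM went from 307 to 21.3 in NCI-H211, 6.95% of the control, from 198 to 60.8 in NCI-H1048 (30.7%), from 501 to 204 in NCI-H526 (40.7%) and from 272 to 218 in COR-L311 (80.4%). Guide-induced changes in the coding sequence can leave the RNA in place, so these values do not measure the protein. Other genes lower in 4 of 4 lines without passing were GRASP at -1.57, RGS2 at -1.37, CHN2 at -1.19, IL13RA1 at -1.15 and PTPN18 at -1.12. Higher in 4 of 4 lines, without passing, were BARX2 at 2.08, CD44 at 1.94, IGFBP2 at 1.66, METTL7A at 1.61, ADGRL2 at 1.19, MYLK at 1.13 and MUC1 at 1.12, all as mean log2 ratios.

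**Figure D1:**
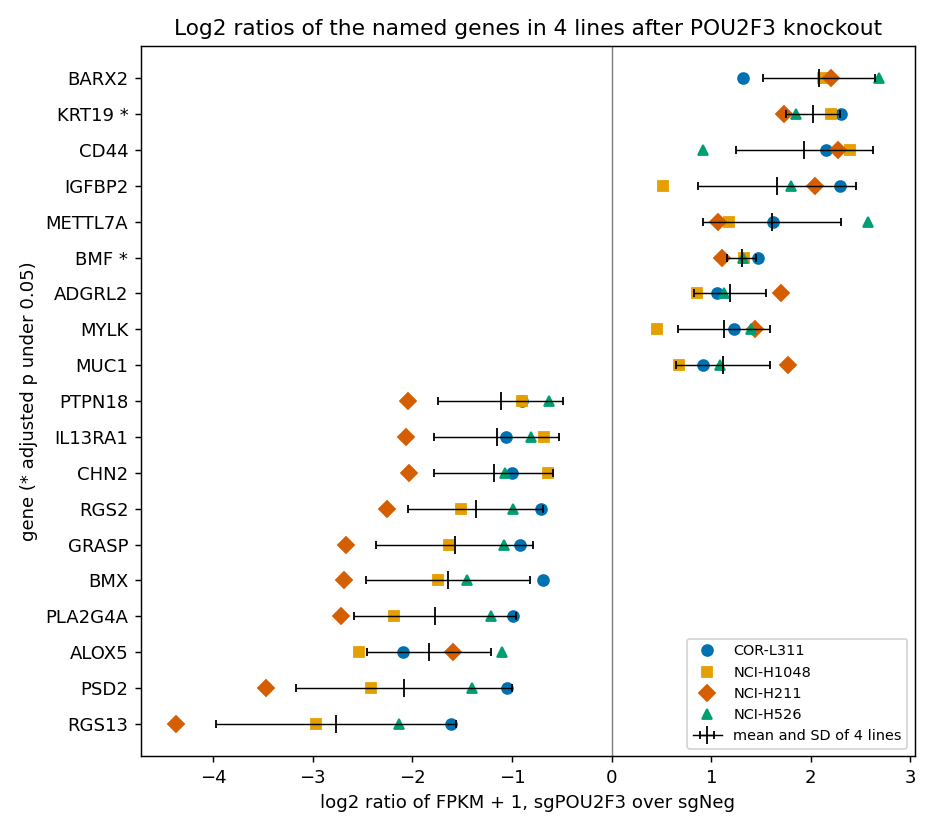
Log2 ratio of FPKM + 1, sgPOU2F3 over sgNeg (x axis), for the named genes (y axis), with 1 symbol per line and the mean and SD of the 4 lines in black. KRT19 and BMF, marked by an asterisk, passed the threshold, and RGS13 has the lowest mean at -2.77.

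Of 12387 genes tested with limma, 2 were higher and 0 lower at the threshold, against 1456 at an unadjusted p of 0.05 (877 lower and 579 higher), where chance gives about 619. In 2815 genes (22.7%) all 4 lines had the same sign, a share that was not set against chance. Genes vary together, so neither this share nor the unadjusted count measures how many genes changed. In 8 genes the ratio reached 2-fold in every line. These were ALOX5, PSD2 and RGS13, lower, and BARX2, BMF, KRT19, METTL7A and SEPP1, higher; SEPP1 was named after its values were seen. The KRT19 and BMF calls were lost on leaving out any 1 line, with adjusted p of 0.051 to 0.31 for KRT19 and 0.069 to 0.34 for BMF, and their mean ratios stayed within 1.93 to 2.12 and 1.25 to 1.37. They were also lost with a pseudocount of 0.1, with no filter and without the trend, and BMF with quantile normalization.

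Gene lists fixed in advance were tested as sets. Of 41 tested genes of the tuft cell list, 0 passed over all genes and 22 were lower and 1 (COLCA1) higher when adjusted over the list alone. The list's median log2 ratio was -0.89 (camera adjusted p = 2.36e-13, and adjusted p = 0.39 with an estimated correlation). Among its members SOX9, a transcription factor of progenitor cells, had ratios of -0.69 to -0.77 in every line (mean -0.73 ± 0.04), SKAP2 a mean of -0.99 ± 0.28, and ALOX5 and RGS13 are given above. Without NCI-H1048, 3 tuft cell genes were higher over the list alone in place of 1, and with no filter 2 were. The eicosanoid list, which shares members such as ALOX5 and PTGS1 with the tuft cell list, had 4 of 8 genes lower when adjusted over the list alone, ALOX5, PLA2G4A, PTGS1 and LTA4H. Its median was -0.71 (camera adjusted p = 0.00018, and adjusted p = 0.39 with an estimated correlation), -0.40 without NCI-H211 and -0.09 with no filter (15 genes, 2 lower and 1 higher over the list alone). Without COR-L311 or NCI-H526, 2 were lower in place of 4. The median of the tuft cell list was -0.71 in COR-L311, -0.59 in NCI-H1048, -1.94 in NCI-H211 and -0.66 in NCI-H526, in each line below all 10000 random lists.

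Another 4 lists passed in the lower direction with the preset correlation, and with neither an estimated correlation nor fry. Of 33 cell cycle genes, 0 passed over all genes and 16 were lower when adjusted over the list alone, among them AURKA at -0.66 ± 0.25, BUB1 at -0.62 ± 0.24, CCNA2 at -0.51 ± 0.16 and AURKB at -0.78 ± 0.42. Without COR-L311, NCI-H211 or NCI-H526 that count was 0, and without NCI-H1048 it was 14. The median was -0.41 (camera adjusted p = 3.45e-09, and adjusted p = 0.39 with an estimated correlation). Of 19 hypoxia and glycolysis genes, 7 were lower and 1 (NDRG1) higher when adjusted over the list alone, with a median of -0.39 (camera adjusted p = 0.00018, and adjusted p = 0.39 with an estimated correlation). HK2, a hexokinase, stood at -0.94 ± 0.23, PDK1 at -0.62 ± 0.07, PFKFB4 at -0.61 ± 0.06 and BNIP3 at -0.58 ± 0.19, while NDRG1 stood at 1.22 ± 0.80. In place of 7, 1 was lower without NCI-H526, 4 without COR-L311 and 11 without NCI-H211, and without NCI-H526 or COR-L311 none was higher. The hypoxia list's median in NCI-H211 was 0.05. Ribosome biogenesis genes had a median of -0.22 (24 genes, 0 when adjusted over the list alone, camera adjusted p = 0.00016, and adjusted p = 0.61 with an estimated correlation), with DKC1 at -0.33 ± 0.18 and a median of 0.01 in NCI-H1048. Cholesterol synthesis genes had a median of -0.18 (20 genes, 0 when adjusted over the list alone, camera adjusted p = 0.0092, and adjusted p = 0.67 with an estimated correlation), with INSIG1 at -0.61 ± 0.41 and a median of 0.05 in both NCI-H1048 and NCI-H211. Without COR-L311 the ribosome biogenesis call (median -0.08, adjusted p = 0.11) and the cholesterol call (adjusted p = 0.070) were lost, and without NCI-H526 the cholesterol call was (median -0.05, adjusted p = 0.51). Without NCI-H1048 the cholesterol median was -0.28, with 3 genes lower when adjusted over the list alone, and with quantile normalization it was -0.11.

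Among the lists that passed in the higher direction, the 15 tested YAP and mesenchymal genes had a median of 0.88 (camera adjusted p = 1.12e-06, and adjusted p = 0.39 with an estimated correlation), with CD44 as the only gene higher when adjusted over the list alone. Without NCI-H211 the median was 0.39, with 1 gene lower over the list alone, and without NCI-H526 3 genes were higher. With a pseudocount of 0.1 the median was 1.33 with 3 genes higher, and 3 were higher with ratios centred on their median and 2 with quantile normalization. The 13 IGF axis genes had a median of 0.62 (camera adjusted p = 0.00020, and adjusted p = 0.39 with an estimated correlation), with IGFBP2, a binding protein of insulin-like growth factors, as the only gene higher when adjusted over the list alone. The median by line was 1.71 in NCI-H211, 0.25 in NCI-H1048, 0.21 in COR-L311 and 0.05 in NCI-H526. Without NCI-H211 it was 0.28, with no filter 0.23, with the filter at an FPKM of 5 0.21 and with a pseudocount of 0.1 0.98. Without NCI-H526 no gene was higher when adjusted over the list alone, and without COR-L311 or with a pseudocount of 0.1, 2 were. IGFBP5 had a mean of 2.36 ± 1.78 and IGFBP3 of 1.88 ± 2.54. The 19 MAPK feedback genes had a median of 0.21 (camera adjusted p = 0.032, and adjusted p = 0.68 with an estimated correlation), with PHLDA1 at 1.18 ± 0.55. Without NCI-H211 that median was -0.03 (adjusted p = 0.72), without COR-L311 it was 0.33, and with quantile normalization the call was lost (adjusted p = 0.084). In all, 9 of 19 tested lists passed with the preset correlation, 6 lower and 3 higher, 0 with an estimated correlation and 0 with fry, where 4 had an unadjusted p under 0.05.

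The other 10 tested lists did not pass. Their medians were -0.69 for taste transduction, 0.44 for the POU2F family and coactivators, 0.09 for neuroendocrine genes, 0.00 for the Notch pathway, -0.03 for epithelial genes, 0.10 for p53 targets, 0.09 for integrated stress, 0.07 for interferon, -0.05 for antigen presentation and -0.02 for apoptosis regulators. The taste median was -0.10 without NCI-H211, and that of the POU2F family was 0.19 without NCI-H526 and 0.21 with no filter or with the filter at an FPKM of 5. Without COR-L311 the median was 0.11 for epithelial genes and 0.04 for apoptosis regulators, without NCI-H211 it was 0.02 for p53 targets, and without NCI-H526 it was -0.02 for interferon. With no filter, taste transduction (lower, adjusted p = 0.028) and interferon (higher, adjusted p = 0.046) passed, as did the basal airway list (higher, 13 genes, median 0.25, adjusted p = 0.0012), which had too few genes otherwise. KRT19 and BMF belong to the epithelial and apoptosis lists, and when adjusted over the list alone BCL2L1, an inhibitor of apoptosis, was higher too (0.55 ± 0.12), as was JAG1, a Notch ligand (1.22 ± 0.62). Without NCI-H1048, NCI-H211 or NCI-H526, and with no filter, no Notch gene was, and without COR-L311 2 were. The epithelial and apoptosis lists had medians below 0 and means above 0. In the POU2F family list, POU2F3 and C11orf53 were lower and COLCA1 and POU2AF1 higher when adjusted over the list alone. Of these 2 and 2, the lower were 0 without NCI-H1048 and 1 without NCI-H211, and the higher 1 without COR-L311 or NCI-H526. With quantile normalization or with no filter, 0 were lower and 1 higher, and with the filter at an FPKM of 5, 1 was higher. C11orf53, COLCA1, COLCA2 and POU2AF1 lie on chromosome 11 between 111245805 and 111455630 (GRCh38). COLCA1 had a mean of 2.77 ± 1.40, and C11orf53 one of -1.63 ± 1.55.

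**Figure D2:**
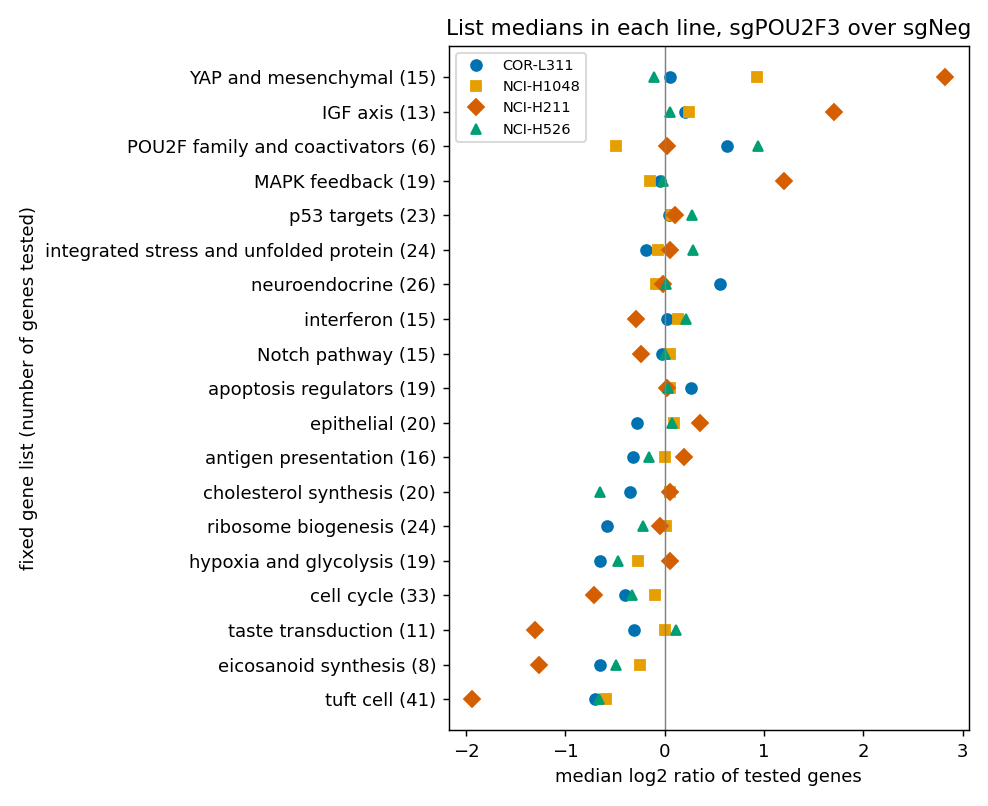
Median log2 ratio of the tested genes, sgPOU2F3 over sgNeg (x axis), for each fixed list (y axis, number of genes in parentheses), with 1 symbol per line. The tuft cell median lies below 0 in all 4 lines, from -0.59 to -1.94, and the YAP and mesenchymal median runs from -0.11 in NCI-H526 to 2.82 in NCI-H211.

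The next comparison asked what changed within each line, by size alone. NCI-H211 had the most genes at 2-fold or more, 528 lower and 603 higher, followed by COR-L311 with 238 and 348, NCI-H526 with 48 and 172, and NCI-H1048 with 97 and 95. In NCI-H211 the bitter taste receptor gene TAS2R38 went from 309 to 11.1 FPKM, RGS13 from 696 to 32.6, and the neural lineage factors OLIG1 from 32.3 to 1.27 and OLIG2 from 44.6 to 2.36. In the same line the YAP target gene CYR61 went from 1.43 to 463 FPKM, AMOTL2 from 0.642 to 143, the keratin gene KRT17 from 1.48 to 384, PRSS23 from 4.77 to 324 and FSTL1 from 4.83 to 326. YAP1, a transcriptional coactivator of the Hippo pathway, went from 1.33 to 56.0 FPKM in NCI-H211 and from 14.6 to 27.6 in NCI-H1048, and was at most 0.588 FPKM in the other lines. The YAP and mesenchymal median was 2.82 in NCI-H211 and 0.93 in NCI-H1048, both at the 100th percentile of random lists, 0.06 in COR-L311 and -0.11 in NCI-H526. TAGLN, on the fibroblast list, was at 50.3 FPKM in NCI-H211 sgPOU2F3, beside COL1A1 at 1.24.

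In NCI-H1048, LRMP went from 53.5 to 4.20 FPKM, CRYM from 93.4 to 8.14, AVIL from 54.95 to 5.28, RGS13 from 50.2 to 5.55 and HEPACAM2 from 19.7 to 2.27. The water channel gene AQP1 went from 8.58 to 96.8 FPKM, the Notch target HES1 from 5.26 to 49.7, IGFBP5 from 4.41 to 44.0, the prostaglandin dehydrogenase gene HPGD from 4.19 to 40.5 and HS3ST3B1 from 3.90 to 34.7. In COR-L311, SLC17A9 went from 19.2 to 3.72 FPKM, ALOX5 from 33.9 to 7.17, TMEM52 from 12.4 to 2.26, IFITM2 from 19.8 to 4.47 and MATK from 96.7 to 26.3. Higher in that line were EYA2 (0.537 to 43.6 FPKM), TMEM176B (1.82 to 63.4), RPRM (0.192 to 19.8), NELL1 (1.11 to 26.9) and DAPL1 (0.483 to 18.2). In NCI-H526, RGS13 went from 73.9 to 16.1 FPKM, CRYM from 269 to 84.6, HBEGF from 47.8 to 16.7, SCIN from 70.9 to 25.3 and BMX from 210 to 76.4. Higher were COLCA1 (2.38 to 64.0 FPKM), ST6GALNAC2 (1.51 to 21.9), PHGR1 (3.42 to 37.1), AKR1C3 (1.88 to 18.3) and the cell cycle inhibitor gene CDKN1C (95.1 to 638).

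NEUROD1, a neurogenic factor, went from 0.173 to 13.8 FPKM in COR-L311 and from 0.107 to 11.6 in NCI-H526, and was listed at 0 in both arms of the other lines. In COR-L311 the neuroendocrine list had a median log2 ratio of 0.56, at the 100th percentile of random lists, and the medians in the other lines lay between -0.09 and 0.01. The differences between lines were not tested, since each line has 1 value per arm.

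**Figure D3:**
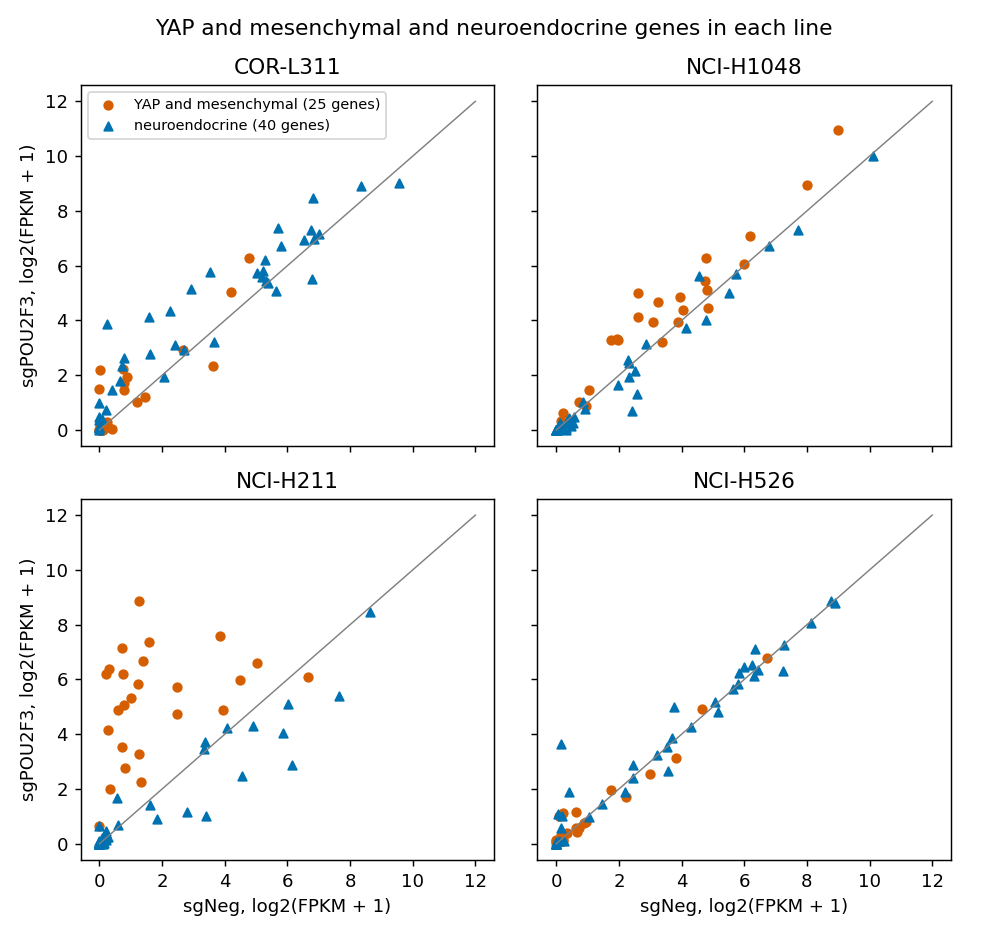
Log2(FPKM + 1) in sgNeg (x axis) against sgPOU2F3 (y axis) in each line, with 1 point per gene of the YAP and mesenchymal list (orange circles, 25 genes) and of the neuroendocrine list (blue triangles, 40 genes), and a grey line where the values are equal. The median log2 ratio of the tested YAP and mesenchymal genes is 2.82 in NCI-H211 and 0.93 in NCI-H1048, with some genes below the line, such as TEAD2 in NCI-H211 and AJUBA in NCI-H1048.

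Across genes, the log2 ratios of each pair of lines had a Pearson correlation of 0.35 for NCI-H1048 and NCI-H211, 0.34 for COR-L311 and NCI-H526, 0.27 for NCI-H1048 and NCI-H526, 0.26 for NCI-H211 and NCI-H526, 0.14 for COR-L311 and NCI-H211 and 0.04 for COR-L311 and NCI-H1048 (12387 genes, which are not independent replicates). The 2 pairs harvested on the same day had the 2 highest values. Of these 6 relations, only that of COR-L311 and NCI-H1048 differed in sign by rank (Spearman -0.02).

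The parental comparison asked how the 4 lines used for knockout differ from 10 other small cell lung cancer lines. POU2F3 was at 188.6 to 387.4 FPKM in the 4 lines and at most 0.608 in the others, a log2 difference of 7.96 (SE 0.29, adjusted p = 9.05e-11, 4 of 4 lines above all 10 others). The labels do not say how the 4 lines were chosen. If they were taken because they express POU2F3, its difference and p follow from that choice and test nothing. The same holds for its part in the lists that contain it. Also past the threshold were RGS13 (difference 7.44, listed at 0 in all 10 others, adjusted p = 3.23e-07), LRMP (7.43), C11orf53 (7.21), BMX (6.61), AVIL (6.35), PLA2G4A (5.38), ASCL2 (5.35), AZGP1 (5.24), GFI1B (5.09), the neuropeptide gene NMU (4.92), PSD2 (4.55), C1orf61 (4.49), PLCG2 (4.29) and SOX9 (4.17). Of these, AZGP1, C1orf61 and PLCG2 overlapped between the groups. AZGP1 was at 1.73 FPKM in NCI-H211 against 16.3 in NCI-H146, and after knockout it was lower in 1 of 4 lines. The difference for RGS13 depends on the pseudocount, since the other lines are at 0. The genes lower in the 4 lines included the glutamate receptor gene GRIK3 (-3.82), CMBL (-3.71), CNRIP1 (-3.40) and PBX3 (-2.94).

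Of 13226 genes tested with limma, 28 were higher and 5 lower in the 4 lines at the threshold, and 1146 had an unadjusted p under 0.05. In 86 genes the 4 lines and the 10 others did not overlap (53 higher, 33 lower), a separation that chance gives for 0.20% of genes. Without COR-L311 the count was 21 in place of 33, and without NCI-H1048 it was 50. The lower genes numbered 18 without DMS114, 11 without NCI-H526, 8 without DMS79 or NCI-H1048, and 3 without COR-L311, NCI-H446 or NCI-H889. The higher genes numbered 18 without COR-L311 or NCI-H526 and 42 without NCI-H1048. Of the 33 calls, 20 (without COR-L311) to 31 (without DMS114 or DMS79) were shared with the fits that left out 1 line, with 22 without NCI-H526 and 24 without NCI-H446. Among named genes, AZGP1 passed only without NCI-H211, NCI-H146 or DMS79, CNRIP1 only without NCI-H526, DMS114, DMS79, NCI-H128 or NCI-H69, and GRIK3 only without NCI-H526, DMS114, NCI-H146, DMS79, NCI-H510 or NCI-H69. The call of SOX9 was lost without COR-L311, NCI-H1048 or NCI-H526, and those of PLCG2 and PBX3 without COR-L311. With a pseudocount of 0.1 the calls of AZGP1 and SOX9 were lost, and with no filter those of AZGP1, CNRIP1 and GRIK3. Directions were kept in these fits.

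The other lines differed in their regulators. NEUROD1 was at 114 FPKM in NCI-H446, 135 in NCI-H82 and 289 in NCI-H524. YAP1 was at 33.7 FPKM in DMS114 and 9.39 in NCI-H1048. The 4 knockout lines had at most 0.400 FPKM of NEUROD1.

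**Figure D4:**
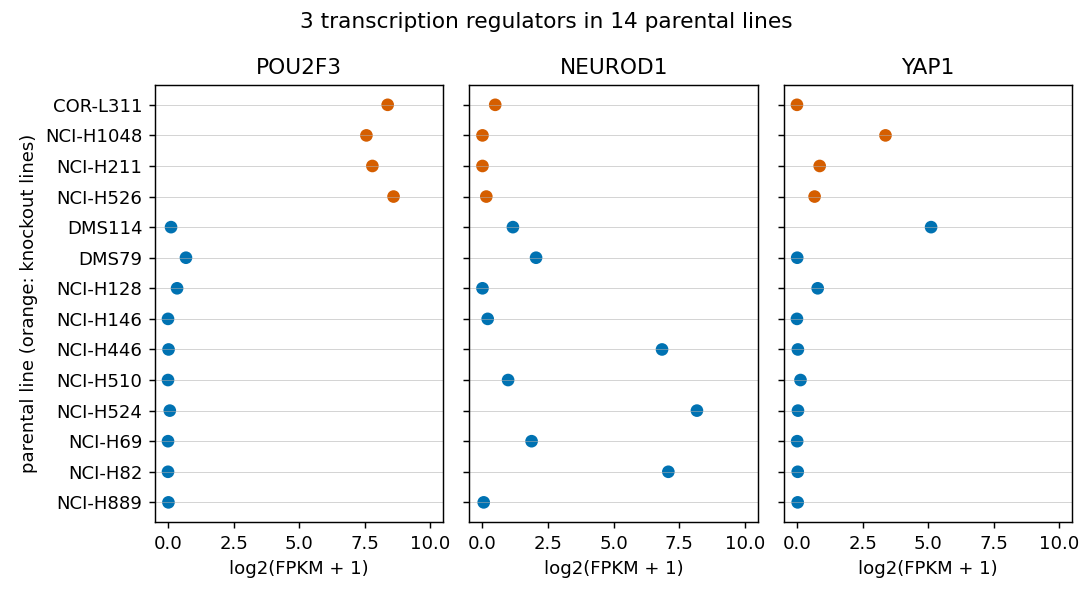
Log2(FPKM + 1) (x axis) of POU2F3, NEUROD1 and YAP1 in 14 parental lines (y axis), 1 library per line, with the 4 knockout lines in orange and the 10 others in blue. POU2F3 is at 188.6 to 387.4 FPKM in the orange lines, and NEUROD1 reaches 289 FPKM in NCI-H524.

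By list, 12 of 37 tested tuft cell genes were higher over all genes, and 29 higher and 1 (ITPR3) lower when adjusted over the list alone, with a median log2 difference of 3.01 (camera adjusted p = 3.04e-44, and adjusted p = 0.00043 with an estimated correlation). The lower count was 0 in 10 of the 14 fits that left out 1 line and with no filter. The POU2F family list, which shares POU2F3 and C11orf53 with it, had a median of 1.30, with 3 genes higher and 1 (POU2F2) lower when adjusted over the list alone (adjusted p = 0.018 with an estimated correlation). Without NCI-H1048 its median was 0.67 with 0 lower, and with no filter the median was 0.22. Neuroendocrine genes had a median of -2.58. Of 40 genes, 0 passed over all genes and 15 were lower when adjusted over the list alone, among them ELAVL4 (-3.36), ELAVL3 (-3.47) and SYT4 (-4.10) (adjusted p = 0.090 with an estimated correlation). In place of 15, 7 were lower without NCI-H1048 or NCI-H211 and 25 without DMS114. Antigen presentation genes had a median of 1.78, with genes such as TAP1 (3.09), TAP2 (2.72), NLRC5 (1.75) and PSMB8 (2.97) higher when adjusted over the list alone (adjusted p = 0.090 with an estimated correlation). The 5 such genes became 0 without COR-L311 or NCI-H526, 3 without NCI-H1048, 9 without DMS114, 10 without NCI-H211 and 8 with quantile normalization, and the median was 1.03 with no filter and 2.83 with a pseudocount of 0.1. Of the eicosanoid list, PLA2G4A passed over all genes, and PTGS1 (3.04) and ALOX5 (3.07) were higher when adjusted over the list alone (median 0.41, adjusted p = 0.071 with an estimated correlation). Without COR-L311 the count of 3 became 1, and the median was 0.25 without NCI-H1048, 0.63 without NCI-H526, 0.22 with no filter, 1.63 with the filter at an FPKM of 5 and 1.03 with a pseudocount of 0.1. Of 10 taste transduction genes, 5 were higher when adjusted over the list alone, TRPM5, GNG13, GNAT3, PLCB2 and TAS1R3, all of them also on the tuft cell list (median 1.24, adjusted p = 0.10 with an estimated correlation). Without NCI-H211 that median was 0.75 with 3 higher, and with a pseudocount of 0.1 it was 1.93. With the filter at an FPKM of 5, the taste median was -0.87 with 2 higher, and the call was lost. Epithelial genes had a median of 1.48, with 0 when adjusted over the list alone and EHF at 3.62 (adjusted p = 0.55 with an estimated correlation). That 0 became 2 without DMS79 and 1 without NCI-H211, NCI-H146 or NCI-H510. In all 7 of 20 lists passed with the preset correlation, 2 with an estimated correlation and 6 with fry.

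The remaining 13 lists did not pass. Their median differences were 0.40 for YAP and mesenchymal genes, 0.29 for Notch (with a mean of 0.03 and a test in the lower direction), -0.84 for basal airway genes, -0.02 for the cell cycle, -0.07 for p53 targets, -0.06 for integrated stress, 0.06 for interferon, 0.21 for ribosome biogenesis, 0.17 for apoptosis regulators, -0.34 for the IGF axis, -0.19 for MAPK feedback (with a mean of 0.19), -0.15 for cholesterol synthesis and -0.39 for hypoxia and glycolysis. When adjusted over the list alone, IGFBP2 (-4.01), IGFBP5 (-4.83) and 2 Notch genes were lower, and BIK (2.80), SPRY1 (1.80), SPRY2 (2.25) and NOTCH1 (2.60) were higher, in the 4 lines. Over the list alone, no Notch or apoptosis gene passed without COR-L311, no apoptosis gene without NCI-H211, and no Notch or MAPK feedback gene without NCI-H1048. The 2 IGF axis genes became 1 in 10 of the 14 fits that left out 1 line, with no filter and without the trend. With a pseudocount of 0.1 no apoptosis gene passed, and with the filter at an FPKM of 5 1 MAPK feedback gene did. The 2 lower Notch genes became 1 with no filter, with that filter and with quantile normalization. Among medians, that of ribosome biogenesis was 0.02 without NCI-H211, of the IGF axis 0.02 without COR-L311, of apoptosis regulators 0.05 without NCI-H69, of the cell cycle 0.02 without NCI-H82 and of hypoxia and glycolysis -0.20 without DMS79.

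The last comparison asked how the genes that set the 4 lines apart behaved after knockout. The 28 higher genes had a median log2 ratio of -1.02 after knockout, with 27 means below 0 and 20 genes lower in 4 of 4 lines. The only mean above 0 was that of LGALS3, at 0.24, which was named after its values were seen. A mean below 0 did not always hold across lines, since AZGP1, at -0.22, was lower in only 1 of 4 lines. When adjusted over the list alone, 19 were lower. The test with a preset correlation gave a camera p of 2.93e-17, and with an estimated correlation the camera p was 0.083. The medians were -0.65 in COR-L311, -0.66 in NCI-H1048, -2.40 in NCI-H211 and -0.71 in NCI-H526, and -0.65 over the lines other than NCI-H211. The set of 19 genes that passed with a pseudocount of 0.1 had a median of -1.67, and the 37 with no filter one of -0.68. Of the 5 lower genes, only PBX3 was expressed enough to be tested, with a mean ratio of 0.62 ± 0.35. The parental and knockout libraries are separate, but 12 of the 28 genes are also on the tuft cell list, so the 2 results overlap. POU2F3, the target of the guides, is 1 of the 28, so its own fall (mean -1.77) is part of these counts and tests.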

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

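The tests of explanations in this part were chosen after the result was seen, except that of another sequenced line as the origin of NEUROD1 and the regroupings of samples.

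In NCI-H211, 21 of 25 YAP and mesenchymal genes were at least 2-fold higher after sgPOU2F3, with a median log2 ratio of 2.82 for those tested. The tables argue against cells of another sequenced parental line, since 11 of the 21 genes were at least 2-fold above the highest of the 13 other lines, such as CAV1 at 191 FPKM against 8.82, although the 2 tables were scaled separately. They argue against fibroblasts, whose most abundant collagens COL1A1, COL1A2 and COL3A1 reached at most 1.96 FPKM against a median of 56.0 among the 21 genes, while DCN, also on the fibroblast list, went from 7.26 to 0.537 FPKM. In the other direction, LUM on that list went from 0.101 to 12.3 FPKM and TAGLN from 3.72 to 50.3. A common scaling factor set by the authors is argued against, since the median log2 ratio over all tested genes was -0.03 in NCI-H211. Quantile normalization gave a list median of 2.72, but it could change little where that overall ratio was already near 0. Cells that were not sequenced here, such as those used to make virus, and an effect of 1 guide alone stay open. A response of this line to loss of POU2F3 may be involved, as a hypothesis that these values do not decide.

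COLCA1 was higher in all 4 lines, with log2 ratios of 0.98 in NCI-H211, 2.47 in NCI-H1048, 3.38 in COR-L311 and 4.27 in NCI-H526. It overlaps COLCA2 on the opposite strand, and the labels name no step that keeps the strand. Spliced COLCA2 reads over the shared exon bases are argued against, since the gain was in the median line 30.9 times what they could add, and at least 12.7 times in each line. Values near the detection limit are argued against too, since COLCA1 rested on an estimated 141 to 594 fragments in 3 of the sgNeg libraries, with the lowest, 27.4, in NCI-H211. Both estimates use GENCODE gene models on GRCh38, with 89 of 8098 COLCA1 exon bases shared. The annotation behind the FPKM is not stated, and other gene models would change these estimates. Unspliced COLCA2 transcripts were not tested and stay open, and no biological explanation was tested.

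NEUROD1 was higher in COR-L311 and NCI-H526, to 13.8 and 11.6 FPKM. Admixed cells of a sequenced NEUROD1 line are argued against, since the other genes such cells would bring reached at most a median of 0.063 of the level needed. The harvest day cannot be told apart from the line: the 2 lines are those of day 5, and the lower of their log2 ratios exceeds the higher of the day 4 lines by 3.51. Nor can the starting level, since parental NEUROD1 was higher in these 2 lines, by at least 0.106 FPKM. A difference between the lines in what they can turn on stays open as a hypothesis.

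Among 64 groups of values for named genes, 12 had 1 line far from the others. The rule used for this would flag about 3 by chance if values were normally distributed. Many groups hold values near 0, so 3 is not the chance count for these data. The log2 ratio of CD44 was 0.92 in NCI-H526 against 2.15 to 2.40 in the other lines. Among the 10 other parental lines, on the log2(FPKM + 1) scale, DMS79 stood apart with POU2F3 at 0.68, BMX at 0.33 and ASCL2 at 2.33, NCI-H69 with LRMP at 3.75, NCI-H82 with PLA2G4A at 3.65, NCI-H146 with AZGP1 at 4.11, NCI-H510 with GFI1B at 0.16 and DMS114 with YAP1 at 5.12. Among the 4 knockout lines, NCI-H1048 stood apart with AVIL at 6.27 and PLCG2 at 1.93, and NCI-H526 with GRIK3 at 3.37.

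For 4 lists the median log2 ratio after knockout lay at or beyond the extreme 2.5% of random lists on either side, on opposite sides in different lines, and these differences were not tested. The POU2F family list was at 0.62 in COR-L311, -0.49 in NCI-H1048 and 0.93 in NCI-H526. Interferon genes were at -0.29 in NCI-H211 and 0.21 in NCI-H526. Antigen presentation genes were at -0.32 in COR-L311, 0.20 in NCI-H211 and -0.16 in NCI-H526. MAPK feedback genes were at -0.15 in NCI-H1048 and 1.20 in NCI-H211.

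The results were set against other groupings of the same samples. For the knockout, the 8 patterns of exchanging sgPOU2F3 and sgNeg within lines are too few for a share under 0.05. The real pattern gave 2 genes against at most 0 in the others (1 of 8 as large), 9 lists against at most 10 (3 of 8), and a median of 1.02 in size for the 28 genes against at most 0.85 (1 of 8). For the parental lines, 2 of 100 splits into 4 and 10, the real one among them, gave at least its 33 genes. That share is under 0.05, but it sets the real split against arbitrary ones. If the 4 lines were taken because they express POU2F3, their split was not arbitrary, and the share cannot decide on chance. Only 100 of 1001 possible splits were drawn, and another gave more genes. The other split gave 94 genes with NCI-H446, NCI-H82, NCI-H524 and DMS114 as the group of 4, and the cause was not tested. For parental lists, 24 of 100 splits gave as many as 7, with at most 11, so chance is not excluded.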

How the results depend on the processing

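All settings here were chosen before the data were examined. The 2 genes higher after knockout became 0 with a pseudocount of 0.1, with no filter, without the trend and with no term for the line. They became 1 with quantile normalization and 0 in every fit that left out 1 line. The cause was not tested, and the fits that left out 1 line also have fewer residual degrees of freedom. The count of lower genes was 0 under every alternative run. The 9 lists after knockout became 0 with an estimated correlation and 0 with fry, and the 7 parental lists became 2 with an estimated correlation; the cause was not tested. With no term for the line, 0 genes after knockout passed when adjusted over the list alone, in any list. With no filter, 12 lists passed after knockout, with taste, interferon and basal airway genes added, and with no term for the line 10, with p53 targets added. Leaving out 1 line gave 9 to 10 and 7 to 9 lists. After knockout, p53 targets then passed without COR-L311, NCI-H1048 or NCI-H211, epithelial genes without COR-L311 and taste genes without NCI-H526. Among parental lists, ribosome biogenesis passed without NCI-H526, NCI-H82, NCI-H524 or DMS114, the IGF axis without NCI-H1048 or NCI-H889, hypoxia without COR-L311 and integrated stress without NCI-H526.

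The 5 parental genes lower in the knockout lines became 13 with a pseudocount of 0.1 and 3 with no filter. Leaving out 1 line gave 3 to 18 lower, 18 to 42 higher and 21 to 50 genes in all. Under the alternatives run, each correlation between lines moved by less than the SD between the pairs. By rank, that of NCI-H1048 and NCI-H211 was 0.26 in place of 0.35, and that of COR-L311 and NCI-H1048 was -0.02 in place of 0.04. The median of the 28 parental genes after knockout lay between -0.65 and -1.22 when 1 line was left out. Where another setting gave another parental set, the median was -1.67 with a pseudocount of 0.1 (19 genes), -0.68 with no filter (37) and -1.30 with the filter at an FPKM of 5 (20).

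Counts at 2-fold within a line depend on low values. With a pseudocount of 0.1 they were 409 lower and 693 higher in COR-L311, 178 and 179 in NCI-H1048, 804 lower in NCI-H211, and 91 and 324 in NCI-H526. With no filter, NCI-H1048 had 149 higher. With the filter at an FPKM of 5, COR-L311 had 176 higher, NCI-H1048 58 lower and 49 higher, NCI-H211 348 higher and NCI-H526 79 higher, since fewer genes were tested.

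Several list tests changed direction, of which only MAPK feedback had passed, and the cause was not tested. With the stricter filter the median after knockout was 0.026 for antigen presentation. Over the fits that left out 1 line, the medians after knockout ran from -0.15 to 0.029 for antigen presentation (above 0 without COR-L311), from -0.032 (without COR-L311) to 0.19 for neuroendocrine genes, from -0.029 (without NCI-H1048) to 0.0092 for Notch, from -0.032 (without NCI-H211) to 0.33 for MAPK feedback and from -0.042 (without NCI-H526) to 0.10 for integrated stress. In the parental comparison, the median was 0.014 for basal airway genes with no filter, and with the stricter filter -0.50 for YAP and mesenchymal genes, 0.60 for Notch and -0.33 for MAPK feedback. Leaving out 1 line gave -0.26 (without NCI-H1048) to 0.82 for YAP and mesenchymal genes, -0.062 to 0.63 for Notch, -0.58 (without NCI-H1048) to 0.10 for MAPK feedback, -0.21 to 0.17 (without COR-L311) for p53 targets, -0.10 (without NCI-H1048) to 0.32 for interferon, -0.24 to 0.086 (without NCI-H211) for integrated stress and -0.36 to 0.043 for cholesterol synthesis. Fits on single guides, with guides as replicates, or with the spread of 1 line, and the test of a difference between lines were not run, since the guides are combined. Estimated depths of 9.68 to 31.5 M fragments limit values near 0.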

Other observations

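The genes in this paragraph were chosen after their values were seen, and each line has 1 ratio. FOXI1, the transcription factor of ionocytes, went from 27.6 to 5.53 FPKM in NCI-H1048 and from 38.8 to 5.38 in NCI-H211, and from 0.314 to 1.71 in COR-L311 and from 0.662 to 5.60 in NCI-H526. INSM1, a neuroendocrine transcription factor, had log2 ratios of 1.68 in COR-L311 and 0.77 in NCI-H526, and of -1.26 in NCI-H1048 and -1.63 in NCI-H211. HES1, a Notch target known to repress neuroendocrine genes, had ratios of 3.02 in NCI-H1048 and 4.12 in NCI-H211, against -0.31 in COR-L311 and 1.10 in NCI-H526. CDKN1C had ratios of 2.35 in COR-L311 and 2.73 in NCI-H526, 0.62 in NCI-H1048 and -1.79 in NCI-H211. SCGB2A1 had ratios of 2.46 in COR-L311 and 1.93 in NCI-H526 and was listed at 0 in both arms of the other lines. The keratin gene KRT8 had ratios of 1.78 in NCI-H1048 and 2.20 in NCI-H211, and -0.30 in COR-L311 and 0.18 in NCI-H526. These pairs of lines are also the pairs that share a harvest day.

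In COR-L311, neuroendocrine genes with high ratios, chosen after their values were seen, were SYT4 at 2.54, CPE at 2.24, TAGLN3 at 2.22 and CELF3 at 2.10, while CHGA stood at -0.57 and TFF3 at -1.28. The 9 lists with too few tested genes in the knockout tables were markers of other cell types, and their most abundant genes were KRT17 for basal airway (384 FPKM, NCI-H211 sgPOU2F3), TPPP3 for secretory and ciliated airway (25.4, COR-L311), CAV1 for alveolar (191, NCI-H211), ATP6V0B for ionocyte (137, NCI-H526), CD79B for B lymphocytes (56.3, COR-L311 sgNeg), LCK for T lymphocytes (10.6, COR-L311), CD68 for macrophages (6.75, COR-L311), TAGLN for fibroblasts (50.3, NCI-H211) and CLDN5 for endothelium (17.8, COR-L311).

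A hypothesis tested here, with both of its tests chosen after related results were seen, is that knockout moves expression toward that of the other parental lines beyond the tuft cell list and the 33 parental genes. Across 12130 other genes, the parental difference and the mean ratio after knockout had a Pearson correlation of -0.31, and -0.25, -0.13, -0.16 and -0.27 in COR-L311, NCI-H1048, NCI-H211 and NCI-H526. Genes near 0 can only rise, and the filter lets in low genes that rose, which could give such a correlation. That is argued against as the whole cause, since it was -0.23 over 9994 genes at an FPKM of 1 or more in every sgNeg column with the parental level held fixed. Genes are not independent replicates, both comparisons share the 4 lines, and the correlation is compatible with the hypothesis but weak. The 12130 genes still held 108 at least 4-fold lower and 162 at least 4-fold higher in the 4 parental lines. After knockout 87.0% and 21.0% of these had a mean ratio above 0, against 46.8% of all. Whether the correlation goes beyond such differences, which the threshold missed, was not tested.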
